A study of Mus musculus with 6 samples.

How the data were processed

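RNA was sequenced from CD4+ and CD8+ cells that were sorted by flow cytometry from the spleens of C57BL/6 mice. The mice had received angiotensin II from osmotic pumps placed under the skin. Per the labels' protocols, RNA was extracted with Trizol and 500 ng per sample went into stranded poly(A) libraries made with the Illumina TruSeq kit. The labels name 3 CD4 libraries (385, 393 and 395) and 3 CD8 libraries (389, 395 and 387), and each library was placed in its group by its label. The number was read as a mouse number, so that 5 mice gave 6 libraries and number 395 gave 1 library of each group, although the labels do not state that the number marks the animal. The gates of the sort beyond CD4 and CD8 are not given in the sources used here. No library from untreated mice was used here, so no comparison addresses the effect of angiotensin II.

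The deposited table holds a signal per gene and library, which the authors made by dividing gene read counts by 1 size factor per library. Per the submitters' processing notes, STAR 2.7.5c, featureCounts 2.0, DESeq2 and the GRCm39 build were used, with no roles given. The annotation and the strand setting of the counting are not given in the sources used here. Whole reads were recovered from the deposited signal values: 100% of the values in every library were whole multiples of the value of 1 read, within a tolerance of 0.001 reads. The implied size factors equalled median-of-ratios factors recomputed from the recovered reads to within 3.1e-15. The table has 17832 genes and the lowest total over the 6 libraries was 11 reads, so genes below that were not analysed here. Because the reference available was an older mouse build (GRCm38), it was used only for gene names and gene order, and no coordinates are given; 17322 of the genes have a symbol found in it. No 2 libraries agreed within sampling noise, since the lowest chi-square per degree of freedom over the pairs was 25.4, over genes with at least 100 reads per pair.

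Recovered reads per library ranged from 10264246 to 14628599. A count of 3 reads, the limit that a count of 0 allows, corresponds to a normalised value of 2.52 to 3.49, depending on the library. Where 1 group held 1 to 3 reads of a called gene in all, a ratio with an exact binomial 95% interval on the reads is given in place of a fold change, and a group at 0 reads gives a lower bound against 3 reads over the group. Such intervals cover counting error only.

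The main test was limma (version 3.58.1, in R 4.3.3) with a mean-variance trend on log2(value + 1), over the 13877 genes with a value of 10 or more in at least 3 libraries, two-sided, with Benjamini-Hochberg adjustment. A gene is called at an adjusted p under 0.05. Fold changes are CD8 minus CD4 on the log2(value + 1) scale, which understates the change of low genes, and are given with the standard error (SE) of the moderated fit. Means are normalised read counts ± SD over 3 libraries. Gene lists, 39 in all with 458 different genes, of which 431 are in the table, were fixed before the data were examined, as were the test, the alternatives and the rule for naming genes. The 38 lists with 3 or more tested members were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists, and again with an estimated correlation and with limma's fry, for a shift in 1 direction and for changes in either direction. The number of called members is given over all genes tested and adjusted over the list alone. Markers of other cell types were also summed per library and compared with an exact two-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1.

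The genes named are the 12 highest in each direction by log2 fold change among called genes with a mean value of 50 or more, ranges that do not overlap between the groups, and a descriptive name; 5 lineage genes (Cd4, Cd8a, Cd8b1, Zbtb7b and Runx3); and, per list, up to 4 called members in each direction or, where fewer than 2 are called, the 2 members with the highest mean value. Not every gene that the rule names is given in the text. Any other gene is named after its values were seen, and mainly in the closing section.

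In simulated reads with the means and depths of the 6 libraries, over 13610 genes, limma recovered 24% of genes changed by 2-fold and 95% of genes changed by 4-fold, with 8 false calls. The changed genes were drawn from those with a mean value of 50 or more, so recovery of lower genes was not measured. On the same simulated reads edgeR recovered 24% and 95% with 7 false calls, and DESeq2 recovered 47% and 98% with 51 false calls. In the simulated list test, 1 of 1 changed lists and 0 of 40 unchanged lists were called. The simulated genes were drawn independently of each other, whereas the T cell receptor list had an estimated correlation of 0.966. That list test therefore gives no rate of false calls for lists whose genes move together. The alternatives planned were other pseudocounts (0.5 and 5), other filters on low values, TMM rescaling and quantile normalisation, other variance models, edgeR's quasi-likelihood test (version 4.0.16) and DESeq2 (version 1.42.0) on the recovered reads, and fits without each library and without both libraries numbered 395. Chosen after the data were seen were a rescaling to the T cell receptor list, the macrophage or the proliferation markers as a covariate, and a block for the shared number with an assumed correlation of 0.5.

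Only number 395 occurs in both groups. The deviations of its CD4 and CD8 libraries from their group means had a correlation of 0.018 across genes, and the 9 pairs of a CD4 and a CD8 library ranged from -0.56 to 0.416. No library of the table was left out of the main test.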

Results

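The libraries profile CD4+ and CD8+ cells sorted from the spleens of mice infused with angiotensin II, the peptide hormone that raises blood pressure. There were 3 CD4 libraries, numbered 385, 393 and 395, and 3 CD8 libraries, numbered 389, 395 and 387. Recovered reads ranged from 10264246 in CD4 393 to 14628599 in CD8 387, and between 17007 and 17613 genes had at least 1 read. The labels describe separate mice only through these numbers, so p-values measure the spread between the libraries. The comparison asks which transcripts differ between the CD8 and the CD4 libraries of treated mice. These libraries also held many transcripts of other spleen cells, as given below.

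Lineage genes differed between the sorted populations. Cd8a, which encodes the alpha chain of the CD8 coreceptor, had a mean of 7327 ± 3139 (SD, n = 3) normalised reads in the CD8 libraries and 24.7 ± 15.3 in the CD4 libraries. Cd8b1, the beta chain, stood at 4809 ± 2248 against 81.6 ± 23.5. Cd4 was at 5260 ± 1130 in the CD4 and 110.6 ± 64.2 in the CD8 libraries, and Zbtb7b, the transcription factor of the CD4 lineage, at 1388 ± 145 against 292 ± 29.4. The log2 fold changes were 8.31 (SE 0.60) for Cd8a, 5.76 (SE 0.41) for Cd8b1, -5.77 (SE 0.50) for Cd4 and -2.24 (SE 0.16) for Zbtb7b, with limma adjusted p of 0.0042, 0.0042, 0.0089 and 0.0042. Runx3, a transcription factor of CD8 cells, had 1055 ± 289 in the CD8 and 828 ± 58.1 in the CD4 libraries and was not called (log2 fold change 0.31, SE 0.22, limma adjusted p = 0.946). Each of the 6 libraries had the coreceptor transcripts of its label. The CD8 389 library had the lowest Cd8a and Cd8b1 of its group, 3871 and 2283, against 10001 and 6590 in CD8 395. Without CD8 395, Cd4 was not called, with a limma adjusted p of 0.058, and its adjusted p ranged from 3.1e-30 to 0.0918 over the alternatives. Zbtb7b was not called after rescaling to the T cell receptor list, where its log2 fold change was -1.59, and its adjusted p ranged from 4.4e-29 to 0.501 over the alternatives.

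**Figure D1:**
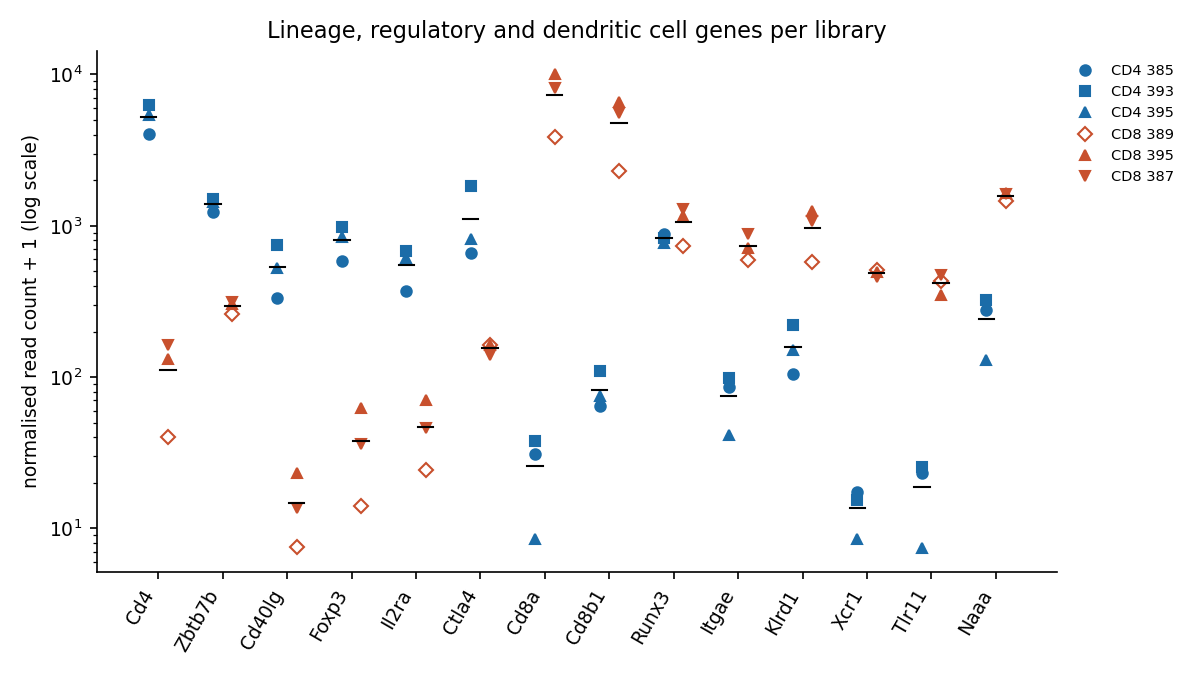
Normalised read count plus 1 (log axis) of 14 genes in each library, with CD4 libraries in blue, CD8 libraries in red, the open diamond for CD8 389 and the black bar at the group mean; Naaa was chosen after its values were seen. Cd4 lies at 4065 or above in the CD4 libraries and at 163 or below in the CD8 libraries, and Xcr1 lies between 456 and 513 in the CD8 libraries and at 16.3 or below in the CD4 libraries.

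Across the 13877 genes tested, limma called 68, of which 39 were higher in CD8 and 29 higher in CD4. All 68 changed by at least 2-fold and had ranges that did not overlap between the groups, as had 10.2% of all genes tested, where chance gives 10%. At an unadjusted p under 0.05 there were 807 genes, where chance gives 694. Among the genes that the naming rule allows, those with the largest fold changes in CD8 after Cd8a were Klra13-ps (log2 fold change 6.76, SE 0.85), a pseudogene of the Ly49 receptor family for which reads shared with related genes were not examined here, and Slc6a19, a transporter of neutral amino acids (6.24, SE 0.48). Cd8b1 came next (5.76, SE 0.41). The 12 highest also held Xcr1, Tlr11, Gcsam and Notch4, and Gpr141b, Pianp, Lcn4 and Fam149a at 5.28 (SE 0.81), 4.97 (SE 0.64), 3.98 (SE 0.42) and 3.89 (SE 0.35). In the CD4 libraries Pdlim4 was higher by a log2 fold change of -3.60 (SE 0.47), and Epas1, a hypoxia-inducible transcription factor, by -2.88 (SE 0.36). Over 22 alternatives Gpr141b lost its call in 10, Epas1 in 7, Klra13-ps in 5, Pdlim4 in 5 and Lcn4 in 3. Pianp lost it in 2 of 18 and Slc6a19 and Fam149a in 0 of 18, and these 3 genes fell below the filter and were not tested when any CD8 library was left out. Without CD8 395 or CD8 387, Gpr141b, Klra13-ps, Lcn4, Pdlim4 and Epas1 were not called. Without CD4 393, Gpr141b, Klra13-ps, Pdlim4 and Epas1 were lost, without CD8 389 Gpr141b and Klra13-ps, without CD4 395 Pdlim4 and Epas1, and without CD4 385 Pianp and Epas1. EdgeR's quasi-likelihood test on the recovered reads called 59 genes, all among the 68, and DESeq2 called 319, with all 68 among them. The count fell to 40 without CD4 385, 19 without CD4 393, 46 without CD4 395 (of which 6 were higher in CD4), 40 without CD8 389, 7 without CD8 395 and 9 without CD8 387; rescaling to the T cell receptor list called 93 genes higher in CD8 and 18 higher in CD4.

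**Figure D2:**
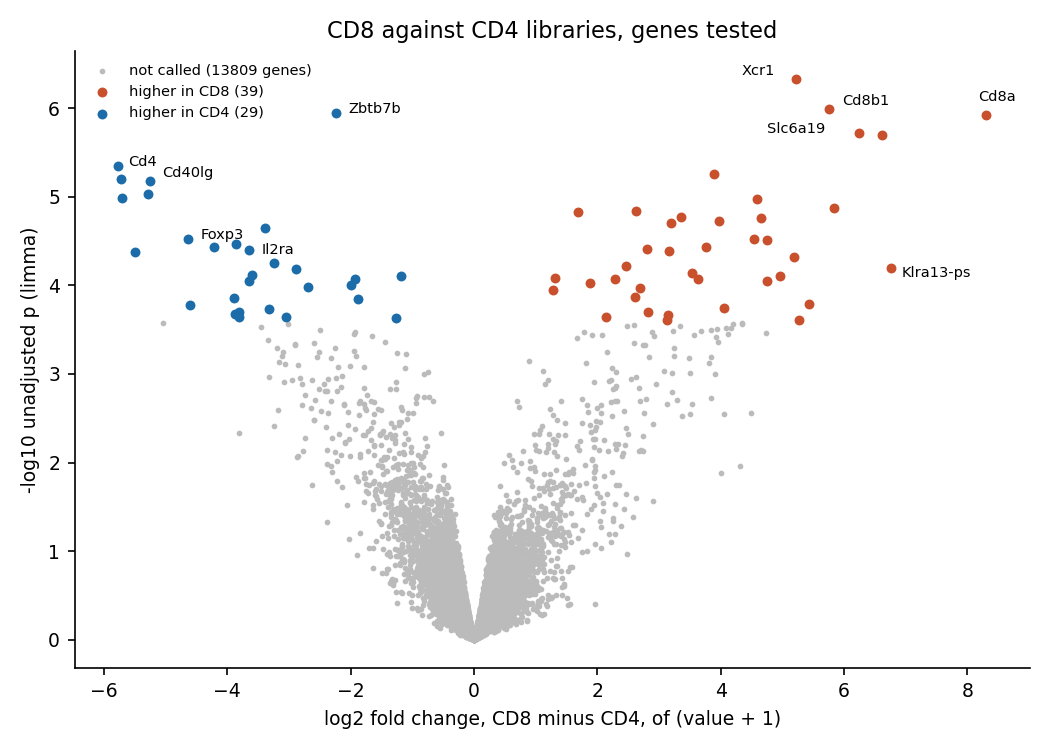
Log2 fold change (CD8 minus CD4, x axis) against the -log10 unadjusted limma p (y axis) of the 13877 genes tested, with 39 genes called higher in CD8 in red, 29 called higher in CD4 in blue and the genes not called in grey.

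Genes of regulatory T cells were higher in the CD4 libraries. Of 15 tested members of this list, 5 were called, all higher in CD4, and 15 passed adjusted over the list alone. Foxp3, the transcription factor that specifies these cells, had 802 ± 203 (SD, n = 3) normalised reads in CD4 and 36.6 ± 24.3 in CD8 (log2 fold change -4.63, SE 0.52). Il2ra, the alpha chain of the interleukin 2 receptor, had 552 ± 163 against 46.1 ± 23.3 (-3.64, SE 0.43). Lrrc32, which holds latent TGF-beta on the surface of these cells, had 361 ± 144 against 8.91 ± 9.05 (-5.49, SE 0.65), and the inhibitory receptor gene Ctla4 had 1106 ± 642 against 155 ± 13.6 (-2.68, SE 0.36). Itgb8, an integrin that releases active TGF-beta, had 194 reads in CD4 and 1 read in CD8, a ratio of 202 with a 95% counting interval of 35.9 to 8029. The list's camera test gave an adjusted p of 3.6e-32 at the preset correlation and an adjusted p = 0.309 with an estimated correlation. The number of called members was 1 without CD4 393, 1 without CD4 395, 1 without CD8 395 and 3 without CD8 387; the filter then also removes genes from the test. EdgeR called 5 members and DESeq2 14.

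Some genes of helper cells and of co-stimulation were higher in CD4. Of the 10 tested members of the CD4 lineage list, 3 were called (9 adjusted over the list alone): Cd4, Zbtb7b and Cd40lg, the ligand through which helper cells activate B cells, with 533 ± 206 (SD, n = 3) in CD4 and 13.7 ± 7.86 in CD8 (log2 fold change -5.25, SE 0.48). The follicular helper list had 3 of 10 called (5 adjusted over the list alone), namely Angptl2 (-3.86, SE 0.44), Tox2 (-3.65, SE 0.48) and Pdcd1 (-3.05, SE 0.46), which encodes the receptor PD-1. Of 12 tested members of the TNF receptor superfamily list, 2 were called (5 adjusted over the list alone), Cd40lg and Tnfsf11, which encodes RANK ligand (-4.22, SE 0.49). The list of inhibitory receptors had Pdcd1 and Ctla4 called in 13 tested (1 higher and 4 lower in CD8 adjusted over the list alone), both higher in CD4. In the Th2 list, 1 of 6 tested members was called (4 adjusted over the list alone), Ccr8, a chemokine receptor, with 118 reads in CD4 and 3 in CD8, a ratio of 41.0 (95% counting interval 13.7 to 202), while Stat6 and Il4ra had log2 fold changes of -0.27 and -0.76 and were not called. The Th1 and Th17 lists had 0 called of 10 and 6 tested (0 and 1 adjusted over the list alone, 2 and 3 at an unadjusted p under 0.05), with 0 and 0 by edgeR and 0 and 1 by DESeq2. Stat4 had 420 ± 90.3 in CD4 and 435 ± 179 in CD8, Il18r1 had 717 ± 208 and 889 ± 355, Stat3 had 2074 ± 347 and 1492 ± 488, and Rora had 199 ± 65.2 and 106 ± 23.3. Camera at the preset correlation called the CD4 lineage, follicular helper, TNF receptor, inhibitory receptor, Th2 and Th17 lists as lower in CD8; with an estimated correlation their adjusted p were 0.309, 0.309, 0.324, 0.651, 0.309 and 0.336. DESeq2 called 5 members of the CD4 lineage list, 4 of the follicular helper, 5 of the TNF receptor and 2 of the Th2 list as higher in CD4, and of the inhibitory receptors 4 as higher in CD4 and 1 as higher in CD8. The follicular helper list had 0 called members without CD4 393, CD8 395 or CD8 387 and 1 without CD4 385, CD4 395 or CD8 389. The TNF receptor list had 0 without CD8 387 and 1 without CD4 385, CD4 393, CD4 395 or CD8 395, and the Th2 list had 0 without any 1 library. Of the inhibitory receptors higher in CD4, 0 were called by limma without a trend, after rescaling to the T cell receptor list, or without CD4 395, CD8 389, CD8 395 or CD8 387, and 1 without CD4 385 or CD4 393, and Pdcd1 and Ccr8 were not called by edgeR (adjusted p = 0.058 and 0.062).

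Genes of CD8 cells and of their natural killer type receptors were higher in the CD8 libraries in part. Of 9 tested members of the CD8 lineage list, 3 were called (6 adjusted over the list alone): Cd8a, Cd8b1 and Itgae, the integrin chain CD103, which some dendritic cells also carry, with 732 ± 145 (SD, n = 3) in CD8 and 74.0 ± 29.7 in CD4 (log2 fold change 3.36, SE 0.35). Of 11 tested natural killer receptor genes, 1 was called (3 adjusted over the list alone), Klrd1, the chain CD94 of inhibitory and activating receptors, with 971 ± 352 against 158 ± 58.0 (2.60, SE 0.37), while Cd226 had 616 ± 220 against 368 ± 127 and was not called. In the list of chemokines and chemokine receptors, 2 of 17 tested members were called, Ccr9, a receptor for homing to the gut, higher in CD8 (695.6 ± 312.8 against 98.1 ± 11.6), and Ccr8, higher in CD4; adjusted over the list alone 2 were higher and 3 lower in CD8. Without any 1 of CD4 385, CD4 393, CD4 395, CD8 395 or CD8 387, Klrd1 and Ccr9 were not called; over all alternatives the adjusted p ranged from 5.9e-09 to 0.373 for Klrd1 and from 1.4e-10 to 0.377 for Ccr9. DESeq2 called 5 members of the CD8 lineage list and 3 natural killer receptor genes as higher in CD8. Over CD8 389, 395 and 387, Itgae had 597, 714 and 885 and did not follow Cd8b1, which had 2283, 6590.4 and 5553. The CD8 lineage list had 5 called members without CD8 389, Itgae was not called without CD8 395 or CD8 387, and Ly6c1 was not called without CD4 393 or CD8 387. The chemokine list's median log2 fold change was 0.58 and its mean 0.00. The cytotoxic effector list had 0 called of 13 tested by limma and edgeR, 3 by DESeq2, 2 without CD8 389 and 5 with library weights. At an unadjusted limma p under 0.05 there were 6, and adjusted over the list alone 3 were higher and 1 lower. Its most abundant members Lamp1 and Srgn had 3288 ± 113 and 1776 ± 70.5 in CD8 against 3021 ± 645 and 1825 ± 107 in CD4. They do not stand for the list, whose log2 fold changes ran from -1.54 to 2.60 with a median of 0.73. In the effector and memory CD8 list, 1 of 13 was called, and it was higher in CD4: Ly6c1, with 470 ± 138 in CD4 and 12.3 ± 7.57 in CD8 (-5.29, SE 0.51). Reads shared between Ly6c1 and the related gene Ly6c2 were not examined here. Itgb1 and Il2rb of that list had 3637 ± 842 and 2602 ± 1168 in CD8 and 3607 ± 726 and 2269 ± 559 in CD4; adjusted over the list alone 2 were higher and 1 lower. Camera at the preset correlation called the CD8 lineage, natural killer receptor, cytotoxic and effector lists as higher in CD8, with an adjusted p of 0.309, 0.338, 0.765 and 0.699 when the correlation was estimated.

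**Figure D3:**
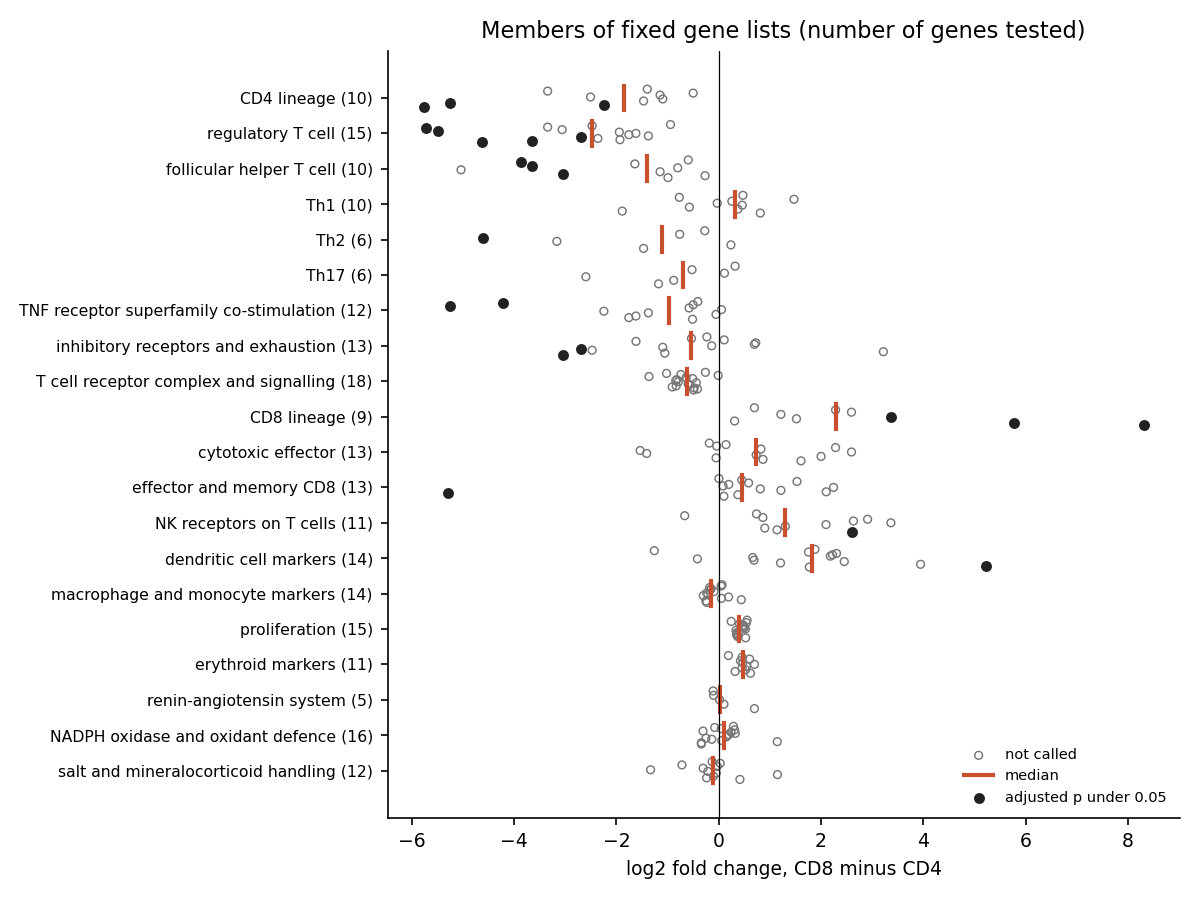
Log2 fold change (CD8 minus CD4) of every tested member of 20 gene lists, with filled points for called genes, open points for genes not called, the red line at the median and the number of genes tested in brackets. All 15 regulatory T cell genes lie below 0, and 5 of them are called.

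Some genes of dendritic cells were higher in the CD8 libraries. Of 14 tested dendritic cell markers, 12 had point estimates above 0, 1 was called and 9 passed adjusted over the list alone, all higher in CD8. The called gene was Xcr1, the chemokine receptor of cross-presenting dendritic cells, with 487 ± 28.4 (SD, n = 3) in CD8 and 12.7 ± 4.66 in CD4 (log2 fold change 5.21, SE 0.33, limma adjusted p = 0.0042). Cd74 and H2-Aa, which encode the invariant chain and a chain of MHC class II, had 14632 ± 3698 and 6517 ± 1005 in CD8 against 4686 ± 2223 and 1614 ± 838 in CD4 and were not called (log2 fold changes 1.76 and 2.18, limma adjusted p = 0.201 and 0.109). Among the 12 genes highest in CD8 stood Tlr11 (4.66, SE 0.49), a receptor for microbial profilin, Gcsam (4.05, SE 0.60) and Notch4 (3.76, SE 0.44). The summed values of the 14 markers were 39143 ± 7218 in CD8 and 10999 ± 5398 in CD4, with a permutation p of 0.1, the smallest that this exact test allows, and 0.433 after adjustment over 13 sums. Camera at the preset correlation gave the list an adjusted p of 1.7e-12, and an adjusted p = 0.336 with an estimated correlation. Without CD8 395 or CD8 387, Tlr11, Gcsam and Notch4 were not called. Gcsam was also lost without CD4 385, CD4 393 or CD8 389, and Notch4 without CD4 393. The number of called dendritic markers was 1 by edgeR, 8 by DESeq2, 8 with library weights, 5 with the assumed block, 9 with the macrophage covariate, 1 with the proliferation covariate and 4 without CD4 395.

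T cell transcripts and those of other spleen cells varied between libraries, and those of other cells were high in every library. Ighm ranged from 62053 to 117988 and the erythroid sums from 28385 to 76477, beside T cell receptor sums of 25049 to 89432. The values are therefore those of mixed libraries, not of T cells alone. The share of each cell type was not measured. The 18 genes of the T cell receptor complex and signalling summed to 68377 ± 21467 (SD, n = 3) in CD4 and 50543 ± 22928 in CD8, with the lowest sum, 25049, in CD8 389 (exact permutation p = 0.5). All 18 point estimates were below 0 and 0 genes were called (1 adjusted over the list alone). Rescaling to this list raised the median log2 fold change of all genes from 0.04 to 0.68, which offsets the list's own median of -0.62; Lck had 5320 ± 1487 in CD4 and 4312 ± 2254 in CD8, and Ptprc, the gene of CD45, had 16540 ± 5893 and 13846 ± 4639. Markers of macrophages and monocytes ranged 6.07-fold between libraries, from 5313 in CD4 395 and 7063 in CD8 389 to 32270 in CD4 385, with Vcam1 at 4947 ± 3477 in CD4 and 3673 ± 1938 in CD8 and Csf1r at 3955 ± 2576 and 3070 ± 1721. Neutrophil markers ranged from 115 in CD4 395 to 6357 in CD4 385, and S100a9 and S100a8 were highest in CD4 385 at 1774 and 1102. Erythroid markers summed to 76477 in CD8 389 and to between 28385 and 57214 in the others, with Car1 at 16904 ± 5123 in CD4 and 18889 ± 4149 in CD8 and Tfrc at 6280 ± 2797 and 8711 ± 4532. Proliferation genes were also highest in CD8 389, at 111626 in sum, with Mki67 at 30040 and Top2a at 11646 there. B cell markers summed to 94978 ± 13222 in CD4 and 98629 ± 30848 in CD8, almost wholly from Ighm (92568 ± 13100 and 96467 ± 30114), while Cd79b had 358 ± 105 and 350 ± 178. Plasma cell markers summed to 13213 ± 1523 and 13438 ± 2896, with Jchain at 11051 ± 1093 and 11169 ± 2695 and Xbp1 at 1493 ± 303 and 1586 ± 88.0. None of these lists had a called member in limma or edgeR. DESeq2 called 1 gene of the T cell receptor list, which also had 1 gene at an unadjusted p under 0.05, and 0 of the others, which had 0.

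**Figure D4:**
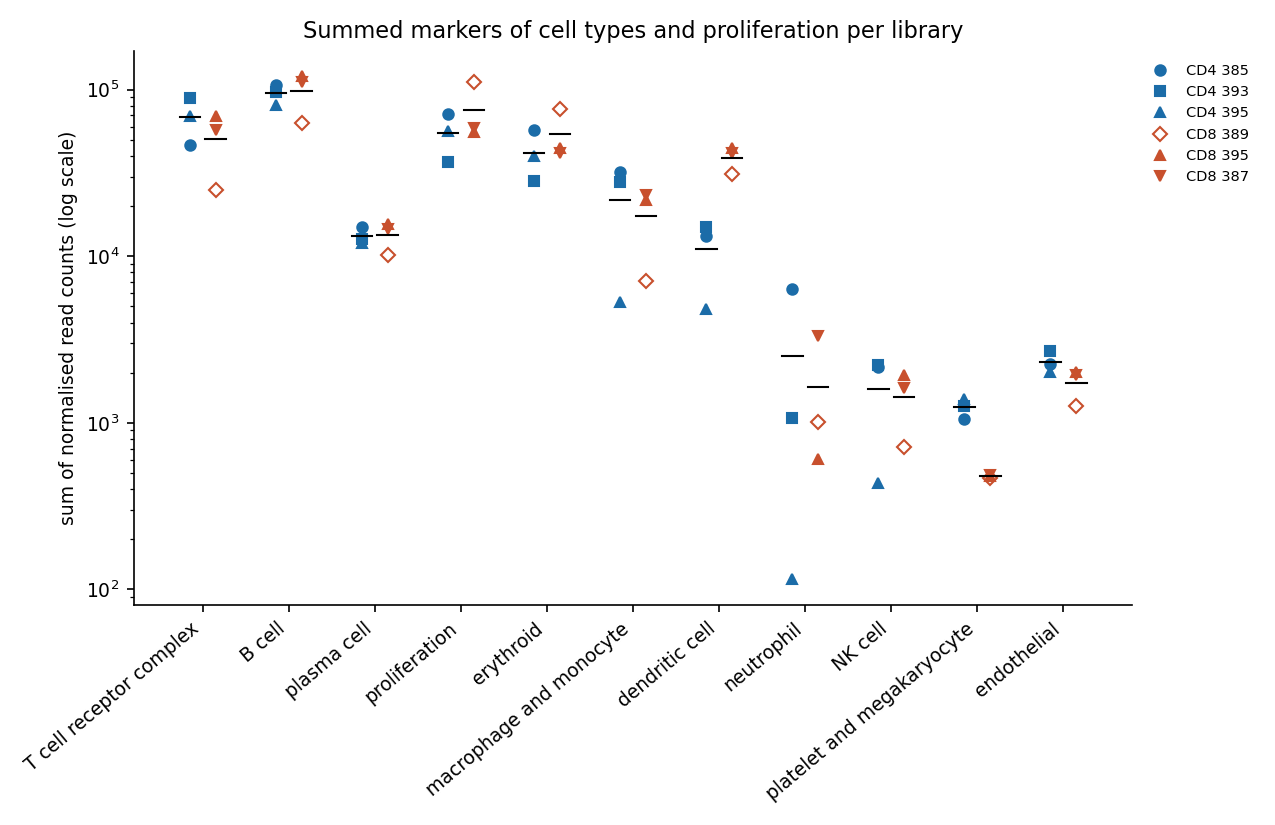
Sum of normalised read counts (log axis) of 11 marker lists in each library, with CD4 libraries in blue, CD8 libraries in red, the open diamond for CD8 389 and the black bar at the group mean. Dendritic cell markers lie between 31061 and 44948 in the CD8 libraries and between 4850 and 14960 in the CD4 libraries.

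Of the remaining cell types, markers of natural killer cells summed to 1607 ± 1014 (SD, n = 3) in CD4 and 1425 ± 638 in CD8, with Tyrobp at 717 ± 490 and 700.3 ± 297 and Fcer1g at 727 ± 456 and 612 ± 327. Tyrobp and Fcer1g hold most of these sums. They were lowest in CD4 395 (151 and 200) and next in CD8 389 (361 and 274), as were the macrophage markers (5313 and 7063). The sums therefore cannot be told apart from macrophage content. Markers of invariant and gamma delta T cells summed to 1178 ± 182 and 1036 ± 253, with Trdc at 414 ± 78.1 and 385 ± 141 and Blk at 258 ± 51.6 and 213 ± 45.7. Platelet markers summed to 1240 ± 170.2 in CD4 and 478 ± 8.99 in CD8 (exact permutation p = 0.1, adjusted 0.433), a difference that came from Itgb3 (992 ± 254 against 186 ± 85.1, log2 fold change -2.50, limma adjusted p = 0.054), since Itga2b had 150 ± 65.0 and 152 ± 36.9. Endothelial markers summed to 2329 ± 334 and 1744 ± 417 (exact permutation p = 0.1, adjusted 0.433), with Pecam1 at 1515 ± 391 and 886 ± 354 and Stab2 at 367 ± 240 and 332 ± 177. Stromal markers were low, at 72.5 ± 35.2 and 51.6 ± 5.78, with 1 tested gene, Pdgfrb, at 50.3 ± 26.3 and 40.8 ± 6.39. The Y-linked genes Ddx3y and Eif2s3y had 1242 ± 172 and 1132 ± 114 in CD4 and 1162 ± 132 and 1195 ± 136 in CD8. None of these lists had a called member in limma or edgeR, and DESeq2 called 1 gene, in the platelet list. At an unadjusted p under 0.05 there was 1 gene each in the invariant and gamma delta, platelet and endothelial lists and 0 in the others. Camera at the preset correlation called the T cell receptor list and the invariant and gamma delta list as lower and the proliferation and erythroid lists as higher in CD8, with an adjusted p of 0.651, 0.336, 0.765 and 0.735 when the correlation was estimated.

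Lists chosen for the treatment showed no called gene. Of 5 tested genes of the renin-angiotensin system, 0 were called by limma, edgeR or DESeq2 and 0 had an unadjusted p under 0.05. Agtr1a, the angiotensin II type 1a receptor, which was chosen after its values were seen, had 98.1 ± 29.7 (SD, n = 3) in CD4 and 173 ± 106 in CD8 (log2 fold change 0.70, limma adjusted p = 0.946), with 295 in CD8 389. Lnpep and Atp6ap2 had 3453 ± 127 and 792 ± 81.7 in CD4 and 3292 ± 833 and 804 ± 122 in CD8. NADPH oxidase and oxidant defence genes had 0 of 16 called, with Rac2 at 8133 ± 1615 in CD4 and 7149 ± 2760 in CD8 and Txnip at 7788 ± 1752 and 6901 ± 3852. Salt and mineralocorticoid genes had 0 of 12 called, with Tsc22d3 at 2534 ± 653 and 2750 ± 1555 and Slc6a6 at 1825 ± 63.7 and 1867 ± 149. Adjusted over each list alone, 0 genes passed in these 3 lists, edgeR and DESeq2 called 0, and 0, 1 and 3 genes had an unadjusted p under 0.05. Fry's test for changes in either direction gave the salt and mineralocorticoid list an adjusted p of 0.0129.

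The other lists held few called genes. The naive and quiescent list had 0 of 13 called (1 adjusted over the list alone), with Tcf7 at 10817 ± 4035 (SD, n = 3) in CD4 and 7209 ± 3450 in CD8. The cytokine list had 0 of 8 called (1 adjusted over the list alone), with Il16 at 2612.5 ± 492 and 1973 ± 857 and Ltb at 2571 ± 869 and 1727 ± 929. In the adhesion list 1 of 18 was called (1 higher and 2 lower adjusted over the list alone), Itgae, while Itga4 had 7530.5 ± 872 and 7917 ± 1622. Immediate early genes had 0 of 16 called, with Hsp90aa1 at 10699 ± 3684 and 12839 ± 4042 and Junb at 5424 ± 1999 and 2480 ± 998. Interferon response genes had 0 of 19 called, with Stat2 at 938 ± 64.9 and 830.3 ± 110.4. MHC class I genes had 0 of 12 called, with H2-K1 at 23818 ± 5625 and 19376 ± 8748 and H2-D1 at 16659 ± 2788 and 14557 ± 5104. Cholesterol synthesis genes had 0 of 16 called. Glycolysis genes had 0 of 15 called, with Gapdh at 6530 ± 911 and 7521 ± 525 and Ldha at 6524 ± 938 and 6428 ± 194. Oxidative phosphorylation genes had 0 of 18 called, with Atp5b at 14721 ± 3943 and 17467 ± 2667 and Atp5a1 at 10824 ± 2369 and 12214 ± 1751. Camera at the preset correlation called the naive, cytokine and immediate early lists as lower and the oxidative phosphorylation list as higher in CD8, with an adjusted p of 0.766, 0.425, 0.346 and 0.778 when the correlation was estimated; the adhesion, interferon, MHC class I, cholesterol and glycolysis lists were not called. The adhesion list's median log2 fold change was -0.08 and its mean 0.01. EdgeR called 0 genes in the naive, cytokine, immediate early, interferon, MHC class I, cholesterol, glycolysis and oxidative phosphorylation lists. DESeq2 called 1 in each of the first 4 and 0 in the rest, and at an unadjusted p under 0.05 there were 2, 3, 6, 5, 0, 1, 0 and 0.

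Number 395 gave the only CD4 and CD8 library with the same label number. For all 68 called genes the CD8 minus CD4 difference of this pair had the sign of the limma fold change, which is not independent of it, since both libraries entered that fit. Of the 100 genes with the smallest p in a fit of the other 4 libraries, 100 had the same sign in the 395 pair. Over all 13877 genes the correlation of the 395 difference with the mean difference of the other 4 libraries was 0.294 (Pearson, across genes, which are not independent replicates) and Spearman's rho was -0.029. The first 3 principal components held 39.1%, 28.1% and 19.7% of the variance between libraries. On the first component the CD8 libraries lay from 12.2 to 59.3 and the CD4 libraries from -48.7 to -0.53. CD4 385 correlated more closely with CD8 387 (0.973 across genes) than with the CD4 libraries 393 (0.963) and 395 (0.951).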

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

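The alternatives named as added, namely the rescaling to the T cell receptor list, the macrophage and proliferation covariates and the assumed correlation, were chosen after the data were seen, as were the tests on other splits of the libraries; the other alternatives were planned. The count of 68 called genes (39 higher in CD8, 29 higher in CD4, all 68 of 2-fold or more) became 104 with a pseudocount of 5 (64 higher in CD8). With the filter at a value of 50 it was 42 (16 higher in CD4), and with no filter 62 genes were higher in CD8. Quantile normalisation gave 126 (73 and 53), library weights 363 (228 and 135, 334 of 2-fold or more) and DESeq2 319 (161 and 158, 303 of 2-fold or more). Added alternatives gave 111 after rescaling to the T cell receptor list (93 and 18), which moved the median log2 fold change of all genes from 0.04 to 0.68, and 169 with the macrophage covariate (122 and 47). A similar or larger count did not always hold the same genes. Of the 68, 50 were kept after that rescaling and 68 with the macrophage covariate. The proliferation covariate gave 83 calls with 55 of the 68 kept, and limma without a trend gave 70 with 52 kept. Leaving out 1 library at a time gave 7 to 46 calls, with 3 to 40 higher in CD8, 4 to 17 higher in CD4 and 7 to 46 of 2-fold or more; the filter then also removes genes that pass it only in the 2 libraries left of a group, and 27 or 28 of the 31 called genes named were tested. Without both libraries numbered 395 there were 3 calls, 3 higher in CD8 and 0 higher in CD4. The cause of the other changes was not tested. No paired analysis was possible because the groups share only 1 number, 395: limma could not estimate the correlation of the planned block. A replicate block with an assumed correlation of 0.5 gave 161 calls (95 and 66, 158 of 2-fold or more).

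Of the 31 called genes named, 4 (Cd8a, Xcr1, Slc6a19 and Fam149a) remained called in every alternative in which they were tested, and 0 changed direction. The 20 lists that camera called at the preset correlation became 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and 0 with fry's test for a shift in 1 direction, where 9 had. Fry's test for changes in either direction called 16 lists, among them the chemokine list (adjusted p = 0.00044), the adhesion list (0.00415) and the salt and mineralocorticoid list (0.0129), which camera did not call. Directions of lists that changed with a call on either side were those of the MHC class I list (adjusted p = 0.042 with the proliferation covariate), the proliferation list with its own genes as the covariate (adjusted p = 0.813) and the neutrophil list without CD4 395 (adjusted p = 0.00404, with a range of 0.000824 to 0.717 over the fits without 1 library); a change of sign without a call on either side was counted as no change. The marker sums and the medians of log2 values differed by more than the spread for 2 lists, the platelet list (-1.36 by sum, 0.09 by median) and the endothelial list (-0.44 by sum, 0.17 by median). The correlation of the 395 difference with that of the other 4 libraries was 0.26 with a pseudocount of 5 and 0.273 with the filter at 50, against 0.294, and the first principal component held 43.8% with that filter, against 39.1%. Over all named genes and alternatives, 1872 values kept their side of the threshold, 127 lost a call and 17 gained one. The 1872 include genes without a call on either side whose sign changed. Il2rb, for example, had a log2 fold change of 0.10 with all libraries and -0.24 without both libraries numbered 395. For lists these counts were 741, 73 and 19, beside the 3 given above. Among the 10 splits of the 6 libraries into 3 and 3, 1 gave 68 genes, the real one, and the highest other gave 0. For lists, 2 of the 10 splits gave 20 or more, with 20 in the real split and 22 in the highest other, which put CD4 385, CD4 393 and CD8 395 together. With 10 splits no share under 0.05 can be reached. Depth limits genes near the filter, where a value of 10 rests on about 10 reads per library.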

Other observations

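All tests of explanations given here were chosen after the results were seen. Several genes called outside the fixed lists, chosen here after their values were seen, were higher in the CD4 libraries. Penk, which encodes the precursor of enkephalins, had 220 reads in CD4 and 2 in CD8, a ratio of 115 (95% counting interval 31.4 to 953). Cish, a feedback inhibitor of cytokine signalling, had a log2 fold change of -1.94 (SE 0.25), St8sia6, a sialyltransferase, -1.88 (SE 0.27) and Ly6a, the stem cell antigen Sca-1, -1.26 (SE 0.19). In CD8, Naaa and Ppt1, both lysosomal hydrolases, had log2 fold changes of 2.80 (SE 0.33) and 1.69 (SE 0.17), Adgrg5 3.54 (SE 0.45) and Apol7c 3.63 (SE 0.48). Gp2 had 89 reads in CD8 and 0 in CD4, at least 28.5-fold higher against 3 reads over the group, and Trabd2b had 104 and 1, a ratio of 99.8 (95% counting interval 17.5 to 3978).

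Of the 7 called genes without a descriptive name, 3 lie within 4 genes of another called gene in the gene order of the GRCm38 annotation. Gm44174 lies within 4 genes of both Cd8b1 and Cd8a. It was higher in CD8 (539 reads against 2, a ratio of 259 with a 95% counting interval of 71.2 to 2140). Gm47050, higher in CD4 (52 reads against 1), is a neighbour of Ccr8, and Gm8221, a pseudogene higher in CD8 (log2 fold change 4.59, SE 0.45), of Apol7c. Gm43914, higher in CD8 (4.54, SE 0.51), lies in an intron of Clec9a on the same strand, so reads of Clec9a transcripts before splicing can enter its count, and Clec9a itself had 762 ± 109.98 (SD, n = 3) in CD8 and 62.5 ± 42.9 in CD4 (3.95, limma adjusted p = 0.054).

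Some dendritic cell genes were higher in the CD8 libraries, with 1 of 14 markers of the fixed list called and 12 of 14 point estimates above 0. A candidate source is the CD8-positive conventional dendritic cell of the spleen, which carries CD8 alpha without CD8 beta and would enter a CD8 sort unless a T cell gate removed it; a T cell gate is not given in the sources used here. A list of 8 further genes of this cell type, recorded as not seen before, had a median log2 fold change of 0.70. This lay above the central 95% (upper bound 0.25) of 10000 random lists matched on mean value. Of the 8, 8 were higher and 1 was called, Cst3 (4614 in CD8, 1084 in CD4). Cst3 is also among the 68 called genes. That it was unseen when listed cannot be shown, so it is not independent support. The random lists hold unrelated genes, while genes of 1 cell type can move together, with an estimated correlation of 0.707 in the fixed dendritic list. The bound can therefore be too narrow and cannot by itself decide for this source. The shift also leans on CD4 395, the library lowest in macrophage markers. Without it the median was 0.37 (upper bound 0.28) and 6 of 8 were higher, with Ckb and Aif1 no longer so, while without any other library the median was 0.57 or more. The most abundant, Cd24a, was high mainly in CD8 389 (19514), with 8840 and 9097 in the other CD8 libraries and 3993 to 11753 in CD4, and is weak support. Of the 8, 6 had a mean of 50 or more in the CD4 libraries too. While 0 of the 8 are in another fixed list, that does not set them apart from other cell types. Aif1, Ckb and Avpi1 were lowest in CD4 395 and next in CD8 389, as were the macrophage sums (5313 and 7063). The others of the 8 were not. Cd24a was highest in CD8 389 and lowest in CD4 393, as were the erythroid sums (76477 and 28385). Part of the shift therefore cannot be told apart from the content of these cell types. A higher share of every myeloid cell type is argued against, since the mean of the 14 dendritic markers of the fixed list, relative to that of the macrophage markers, was higher in CD8 by 1.83 on the log2 scale, with all CD8 libraries (-0.86 or above) beyond all CD4 libraries (-1.72 or below). Expression by the CD8 T cells themselves cannot be told apart: the SD relative to Cd8b1 over the 3 CD8 libraries was 0.914 times the SD of the fixed list itself, but 4.05 times in a set of 20 dendritic genes, some of them picked after their values were seen. The answer differs between the gene sets, and the spread of the fixed list comes from CD8 389. Without that library its own SD fell from 0.429 to 0.0801 and its SD relative to Cd8b1 from 0.392 to 0.0946, both below the within-group SD of the median gene (0.324).

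Rn18s, the gene of the 18S ribosomal RNA, took 2.79% of the reads of the CD8 395 library and 0.0764% to 0.409% in the others. A candidate cause is ribosomal RNA carried into that poly(A) library, since mt-Rnr1 and mt-Rnr2, the mitochondrial ribosomal RNAs, were also higher there, by a median of 2.704 on the log2 scale over the median of the other libraries. Carry-over of RNA without poly(A) tails in general is argued against only weakly, by 38 small nucleolar RNA and histone genes with a median of 0.35 (quartiles -0.12 and 0.98). The upper quartile lay just under 1, the limit chosen for this test. Rmrp, which also lacks a tail, went the other way, with 91.8 there and at most 11.1 elsewhere. The Rn18s share exceeded the highest share in another library by 2.77 on the log2 scale. A size factor divides all genes of a library alike and leaves the share of reads as it is. It could not have made this difference, which follows from how the share is defined and is not the result of a test. No biological explanation was tested.

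The CD8 389 library had fewer T cell transcripts than the other CD8 libraries, with a median deviation of -1.45 on the log2 scale from their mean and 18 of 18 genes of the T cell receptor list lower. A shallower library is argued against, as it ranks 3 of 6 by reads. A lower share of T cells with every other cell type raised alike is argued against too, because erythroid markers (median 0.80) and macrophage markers (-1.93) moved apart by 2.74. The erythroid list (0.80) and the proliferation list (0.82) both lay above the central 95% of 2000 random lists matched on mean value (upper bounds 0.42 and 0.39). These bounds can be too narrow, since the random lists hold unrelated genes. The estimated correlation was 0.589 within the erythroid and 0.949 within the proliferation list. More cycling erythroid cells added to an otherwise equal cell mix, as the whole cause, are argued against. Such cells lower every other type alike, and plasma cell genes (median -0.60) fell less than T cell receptor genes by 0.85. Whether the mix was otherwise equal was not tested. Ighg1, an immunoglobulin gene, had 10247 in CD8 389, 416 in CD8 395 and 5606 in CD8 387. B cell genes had a median of -0.87 and dendritic markers of -0.50, and the quartiles of the B and plasma cell genes lay apart from those of the T cell receptor genes. A part played by erythroid cells stays open, as does a difference between mice, which was not tested.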
